A study of Mus musculus with 12 samples.

How the data were processed

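RNA from the left ventricular free wall was measured on Affymetrix whole-genome mouse arrays, per the design text and the labels, in 12 samples of 4 groups, with 3 arrays from 3 separate mice in each. The deposited values hold, for each of 45101 probe sets and 12 arrays, an intensity on a linear scale that the authors had already scaled: from the values, the mean of each array without its lowest and highest 2% of probe sets lay at 500 on every array (499.8 to 499.84). The algorithm that made the signals and its background correction are not given in the sources used here. All 12 columns were used.

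The groups were sex by treatment, per the labels. The design text mentions arrays for females only, while the labels give 6 female and 6 male arrays, and the expression of Xist and of Y-linked genes was checked against each label. Replicate numbers were not taken to pair arrays. Probe sets were named by the gene symbols of the array annotation; 34958 carried 1 symbol, 932 several and 9211 none, and the gene identifiers of 34754 were found in RefSeq gene records of assembly GRCm38.p6, with 0 symbols updated. Values were taken as log2(intensity + 6.964), where 6.964 is the 10th percentile of all values, without further normalization. The 64 control probe sets were left out, and of the other 45037 those with a mean over 12 arrays above the median (6.51 on the log2 scale, a signal of 83.98) were tested, 22518 in all. Of these 20088 carried 1 symbol, for 11502 genes, and a gene was represented by its brightest probe set.

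Differences were tested with limma 3.58.1 in R 4.3.3 on the 4 group means, with 8 residual degrees of freedom, moderated variances with an intensity trend, and Benjamini-Hochberg adjustment over all probe sets at 0.05, two-sided. The comparisons were verapamil minus vehicle in females, in males and averaged over the sexes, the female minus the male effect, and male minus female vehicle mice. Gene lists for heart muscle function, metabolism, stress responses and cell types (39 lists) were tested with camera of limma at a preset correlation of 0.01, and again with the correlation estimated from the data, where a list had at least 5 measured genes (34 lists), with adjustment over the lists. A list's score on an array is the mean deviation of its genes from their means over the arrays. The groups, comparisons, tests, lists and most alternatives were fixed before the data were examined.

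Named genes were chosen by rule: the 12 largest rises and 12 largest falls past the test without overlap of the groups, 1 probe set per gene; in a comparison with under 10 genes past the test, the 5 of smallest p in each direction; up to 4 members of smallest p in the direction of each list past camera; and 17 genes of the L-type channel, calcium handling and hypertrophy, of which 16 were tested, with Xist and Y-linked genes for the sex comparison. Other genes, chosen after their values were seen, are Myl7, Myl4, Sln, Car3, Adipoq, Fabp4, Lipe, Cyfip2, Iqcg, Trim68 and the genes that escape X inactivation. Ddx3y was named by no tested probe set.

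The pipeline was tested on simulated data. For the female comparison, with 50 genes changed at each size, independent noise gave calls for 10%, 30%, 62% and 82% of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold, and the residuals of these arrays, reassigned to the groups at random, gave 0%, 24%, 64% and 80%. Of 22318 unchanged probe sets, 4 and 3 were called.

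The alternatives were pseudocounts of 1 and 25.17 (the 25th percentile), quantile normalization, no filter and a filter at the 75th percentile, no intensity trend, array weights, only the arrays of the groups compared, replicate number as a block within sex, other probe sets of a gene or their mean, an estimated correlation for camera, and each array left out in turn. Added after seeing the data were the analyses without the 3 arrays of highest actin 3' to 5' ratio, without the 3 arrays of highest atrial markers and with the actin ratio as a covariate. Files were read with the R package data.table (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.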

Results

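Gene expression was measured in the free wall of the left ventricle of ICR mice, an outbred stock, aged 12 to 14 weeks. Verapamil blocks the L-type channel that lets calcium into heart muscle cells at each beat. It was given for 24 h at 3.6 mg per kg per day from a pump placed under the skin, and control mice received the vehicle, 0.02% ascorbic acid. The 12 arrays made up 4 groups of 3 (female vehicle, female verapamil, male vehicle and male verapamil). The design text gives each group as 3 separate mice, but it mentions arrays for females only. Arrays are named by group and replicate number, and the female vehicle array without a number in its label was called 1.

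Each array held 45101 probe sets, of which 22518 were bright enough to be tested, for 11502 named genes. The median signal of an array lay between 81.67 and 109.7, and the correlation of log2 values between pairs of arrays lay between 0.93 and 0.975. The number of arrays limited the precision, with a median standard error of 0.26 log2 units for a change within 1 sex. The actin 3' to 5' signal ratio, a measure of RNA and labelling quality, was 2.08 in female vehicle 1, 1.77 in female verapamil 1 and 2.24 in male vehicle 1, against 1.35 to 1.63 in the other 9 arrays. These 3 arrays also lay apart on the first component of variation (25% of the variance) and had the highest scores of red blood cell markers, at 0.70, 1.75 and 0.83 log2 units. Male verapamil 1 had the highest actin ratio of the other 9 arrays, 1.63, so that the array called 1 was highest in every group. Genes of atrial muscle were high in female vehicle 3, female verapamil 3 and male vehicle 1, where Myl7, the atrial myosin light chain, reached 11.48, 13.6 and 11.45 log2 units, against 8.06 to 9.32 elsewhere. The brightest probe set of an array gave signals of 36216 to 45001 in male verapamil arrays and 43997 to 55448 in the other 9.

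**Figure D1:**
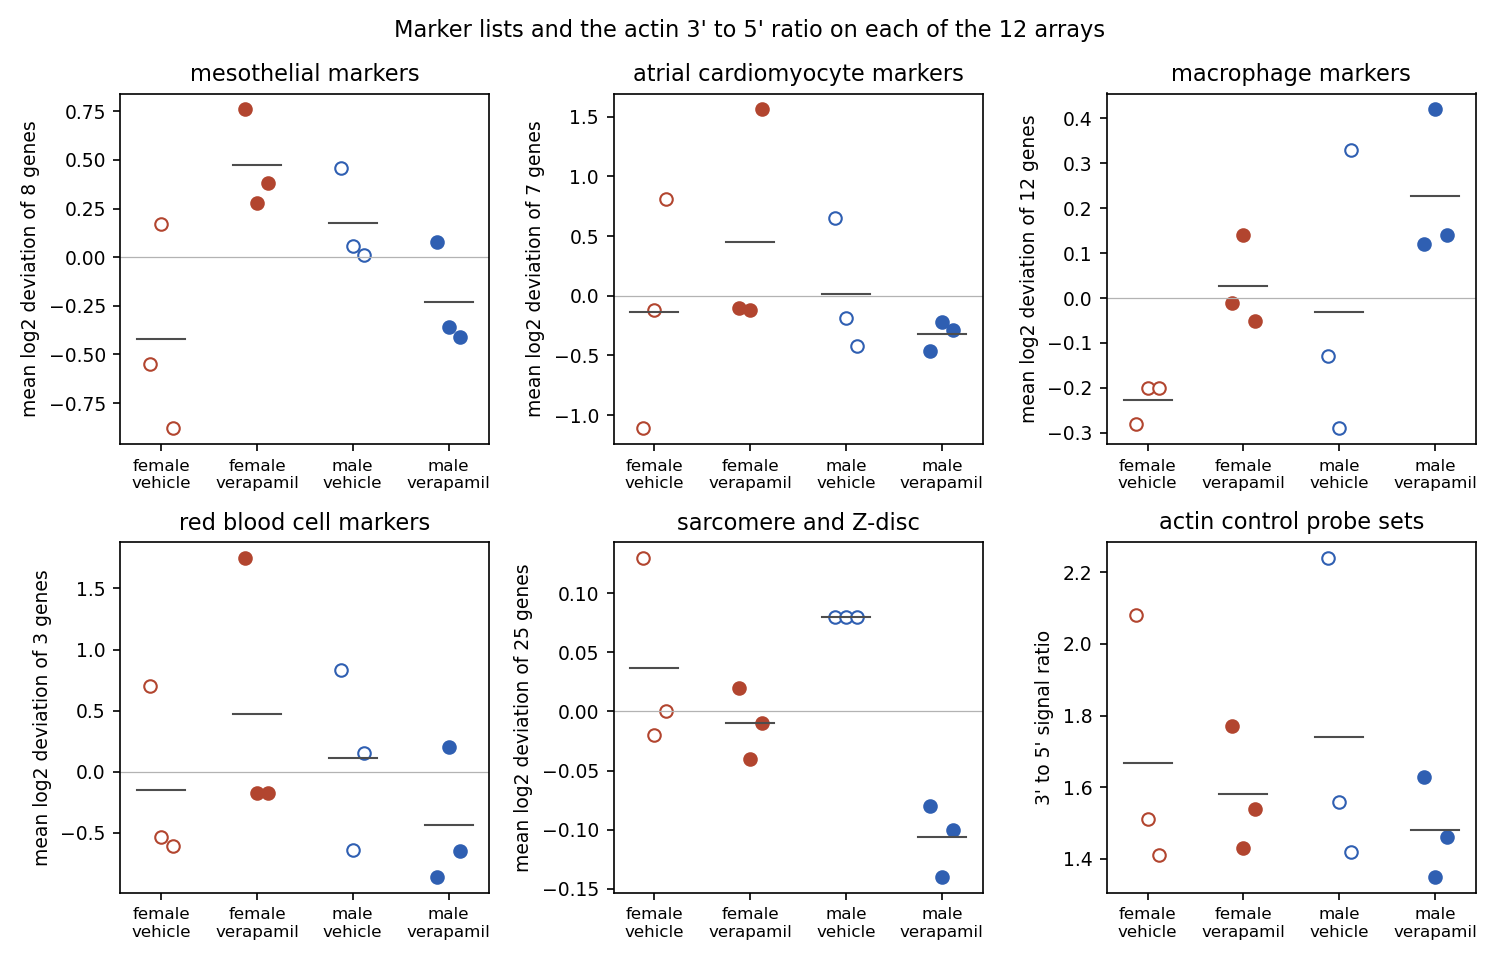
Each point is 1 array, with its group on the horizontal axis and, in each panel, an array measure or a marker score in log2 units on the vertical axis, and horizontal lines are group means. The actin 3' to 5' ratio is highest in female vehicle 1, female verapamil 1 and male vehicle 1 (2.08, 1.77 and 2.24), and the atrial score in female verapamil 3 (1.56).

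The first comparison asked what 24 h of L-type channel block did in the female ventricle. Markers of the mesothelium, the cell layer that covers the heart, rose together: all 8 measured genes were higher under verapamil, by a median of 1.01 log2 units (camera, adjusted p = 5.33e-11; adjusted p = 0.23 with an estimated correlation). Upk3b, a membrane protein of mesothelial cells, had 10.93 ± 0.51 log2 units in vehicle and 12.48 ± 0.10 in verapamil females (mean ± SD, n = 3), and the differences were 1.47 (SE 0.42) for Lrrn4, 1.08 (SE 0.34) for mesothelin, Msln, and 0.96 (SE 0.31) for the keratin Krt19. The mesothelial score was -0.42 ± 0.54 in vehicle and 0.47 ± 0.25 in verapamil females, and 3 of 3 verapamil arrays lay above every vehicle array. Of the 8 genes, 5 passed when adjusted over the list alone.

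Genes of the NRF2 and xenobiotic response rose in females as well, with 12 of 15 members higher and a median of 0.15 (adjusted p = 0.00171; adjusted p = 0.374 with an estimated correlation; 3 of 3 arrays above every vehicle array). The members with the largest differences were Cyp2e1, a cytochrome P450 enzyme, at 7.55 ± 0.40 in vehicle and 9.50 ± 0.52 in verapamil females, and Abcb1b, a P-glycoprotein pump that exports drugs from cells, at 6.70 ± 0.08 and 7.99 ± 0.09. Both passed when adjusted over the list alone. The score of fat cell markers, which had too few measured genes for camera, moved the same way. It went from 0.35 ± 0.11 to 0.76 ± 0.16 in females, with 3 of 3 verapamil arrays above every vehicle array, and from -0.85 ± 0.67 to -0.26 ± 0.52 in males. In the males Cyp2e1 was highest in male vehicle 3 and male verapamil 1 (8.19 and 9.07 log2 units), which also had the highest scores of their groups (-0.08 and 0.21). Macrophage markers rose by a median of 0.23, with 12 of 12 members higher and 3 of 3 verapamil arrays above every vehicle array (adjusted p = 1.62e-04; adjusted p = 0.571 with an estimated correlation). Among them Lyz2, the macrophage lysozyme, differed by 0.41 (SE 0.17), Adgre1, the F4/80 antigen, by 0.42 (SE 0.22) and Fcgr1, an Fc receptor, by 0.39 (SE 0.29). The NRF2 call ended without female verapamil 2 (median 0.08), the median was 0.23 without female vehicle 2, and the call also ended without the 3 arrays of highest actin ratio (median 0.12; adjusted p 0.000341 to 0.122 over the alternatives). Of 14 alternatives, with the estimated correlation set aside, 11 kept the NRF2 call and all 14 the macrophage and mesothelial calls.

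Interferon response genes rose by a median of 0.28 in females, with 19 of 22 higher (adjusted p = 0.00208; adjusted p = 0.769 with an estimated correlation). They included Irf9 at 0.50 (SE 0.27), Oasl2 at 0.40 (SE 0.26) and Bst2, tetherin, at 0.32 (SE 0.21). Fibroblast markers rose by 0.16, with 10 of 11 higher (adjusted p = 0.0167; adjusted p = 0.723 with an estimated correlation). Their members Tcf21, a transcription factor of cardiac fibroblasts, Dpt and Mfap5 differed by 0.38 (SE 0.19), 0.25 (SE 0.14) and 0.52 (SE 0.30). Extracellular matrix genes rose by 0.12, with 22 of 33 higher (adjusted p = 0.0301; adjusted p = 0.854 with an estimated correlation), and the inhibitors of matrix proteases Timp2 and Timp1 differed by 0.48 (SE 0.20) and 0.61 (SE 0.28). Of the 3 verapamil arrays, 2 lay above every vehicle array in the interferon, fibroblast and matrix scores. In the fibroblast and matrix scores 1 lay below every vehicle array. The interferon call ended without female vehicle 3 or female verapamil 2 (medians 0.16 and 0.16) and without the 3 arrays of highest atrial markers (0.11). The fibroblast and matrix calls ended without female vehicle 1 (0.14 and 0.05), female vehicle 3 (0.10 and 0.10), female verapamil 1 (0.16 and 0.02) or female verapamil 2, where the medians turned to -0.07 and -0.13. Their medians were 0.25 and 0.20 without female vehicle 2 and 0.31 and 0.37 without female verapamil 3, and both calls ended without the 3 arrays of highest actin ratio (0.11 and -0.02). Of the 14 alternatives 11 kept the interferon call, 8 the fibroblast call and 4 the matrix call, which also ended with no filter (0.10), no intensity trend (0.12), the mean of all probe sets of a gene (0.12) and the actin ratio as a covariate (0.05).

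Genes of the respiratory chain and ATP synthase rose by a median of 0.06 in females, with 54 of 66 higher, and their median was -0.003 after quantile normalization (adjusted p = 0.0187; adjusted p = 0.867 with an estimated correlation). Ribosomal protein genes rose by 0.11, with 34 of 37 higher (adjusted p = 8.91e-04; adjusted p = 0.769 with an estimated correlation). Examples were Rpl22 at 0.23 (SE 0.16) and Rps18 at 0.21 (SE 0.18). Of the 3 verapamil arrays, only female verapamil 3 lay above every vehicle array in the respiratory and ribosomal scores. Calcineurin, NFAT and MEF2 signalling genes, which couple calcium to transcription, fell by a median of 0.13, with 18 of 22 lower (adjusted p = 0.0263; adjusted p = 0.723 with an estimated correlation). Among them the calcineurin subunit Ppp3r1 differed by -0.27 (SE 0.17), the transcription factor Mef2c by -0.25 (SE 0.19) and Rcan1, a target and inhibitor of calcineurin, by -0.25 (SE 0.17); the other probe set of Ppp3r1 had the opposite sign. The atrial score was 1.56 in female verapamil 3 and 0.81 in female vehicle 3; without the first the respiratory and ribosomal medians were -0.08 and -0.05 and the calcineurin call ended (-0.03), and without the second they were -0.01 and 0.06 and both calls ended. The calcineurin call also ended without female vehicle 1 (-0.11) or female verapamil 2 (-0.15); its median was -0.23 without female verapamil 1, the ribosomal median 0.18 and 0.22 without female verapamil 1 or 2, and the respiratory median 0.10, 0.10, 0.115 and 0.15 without female vehicle 1, female vehicle 2, female verapamil 1 or female verapamil 2. Of the 14 alternatives 8 kept the respiratory call, 11 the ribosomal call and 9 the calcineurin call. Without the 3 arrays of highest atrial markers the first 2 medians turned to -0.15 and -0.125 and the calcineurin call ended (-0.06). The calcineurin call also ended with the mean of all probe sets of a gene (-0.06), and the respiratory call with no filter and with no intensity trend (0.06 in both).

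No single gene passed the limma test in females: 0 of 22518 probe sets had an adjusted p under 0.05, and 510 (2.26%) had an unadjusted p under 0.05, 299 higher and 211 lower, where chance alone gives 1126. The smallest p-values belonged to Abcb1b (1.29, SE 0.25), Igfbp6, which binds insulin-like growth factors (0.90, SE 0.19), Tmem119 (0.86, SE 0.18), Dmkn (2.56, SE 0.57) and, near the floor of the array, the Y-linked Eif2s3y (3.30 and 5.05 log2 units), all higher. In the other direction stood Klhdc4 (-1.21, SE 0.25), the glutamate transporter Slc1a1 (-1.51, SE 0.38), C330022C24Rik (-1.49, SE 0.38), Zfp113 (-1.01, SE 0.27) and Scarb2, a lysosomal membrane protein (-0.56, SE 0.16). Each had an adjusted p of 1, although the 3 arrays of each group did not overlap, which chance gives for 10% of genes.

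The channel that verapamil blocks and the calcium handling genes of the cardiomyocyte gave no adjusted p under 1 in females. Cacna1c, the pore-forming subunit of the L-type channel, was at 11.61 ± 0.10 in vehicle and 11.30 ± 0.57 in verapamil females (-0.31, SE 0.24), and its partners Cacna2d1 and Cacnb2 differed by -0.25 (SE 0.18) and -0.11 (SE 0.21). The ryanodine receptor gene Ryr2 differed by -0.13 (SE 0.15), the calcium pump gene Atp2a2 by 0.06 (SE 0.13) and its inhibitor Pln by 0.03 (SE 0.14). Camk2d, a calcium-dependent kinase, differed by -0.27 (SE 0.18) and the sodium-calcium exchanger Slc8a1 by -0.25 (SE 0.42). The natriuretic peptide gene Nppb, a marker of wall stress, was at 13.11 ± 0.56 and 12.42 ± 0.52 (-0.69, SE 0.32), while Nppa differed by 0.26 (SE 0.80). Myosin heavy chains Myh6 and Myh7 differed by -0.01 (SE 0.12) and -0.25 (SE 0.43), and Rrad, Kcnip2 and Gja1 by 0.04 (SE 0.33), -0.07 (SE 0.17) and 0.04 (SE 0.16). The other probe sets of Ryr2, Slc8a1 and Kcnip2 had the opposite sign. Cacna2d1, Atp2a2, Gja1 and Camk2d had 2, 3, 3 and 2 other probe sets of opposite sign and 1, 1, 2 and 2 of the same sign.

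**Figure D2:**
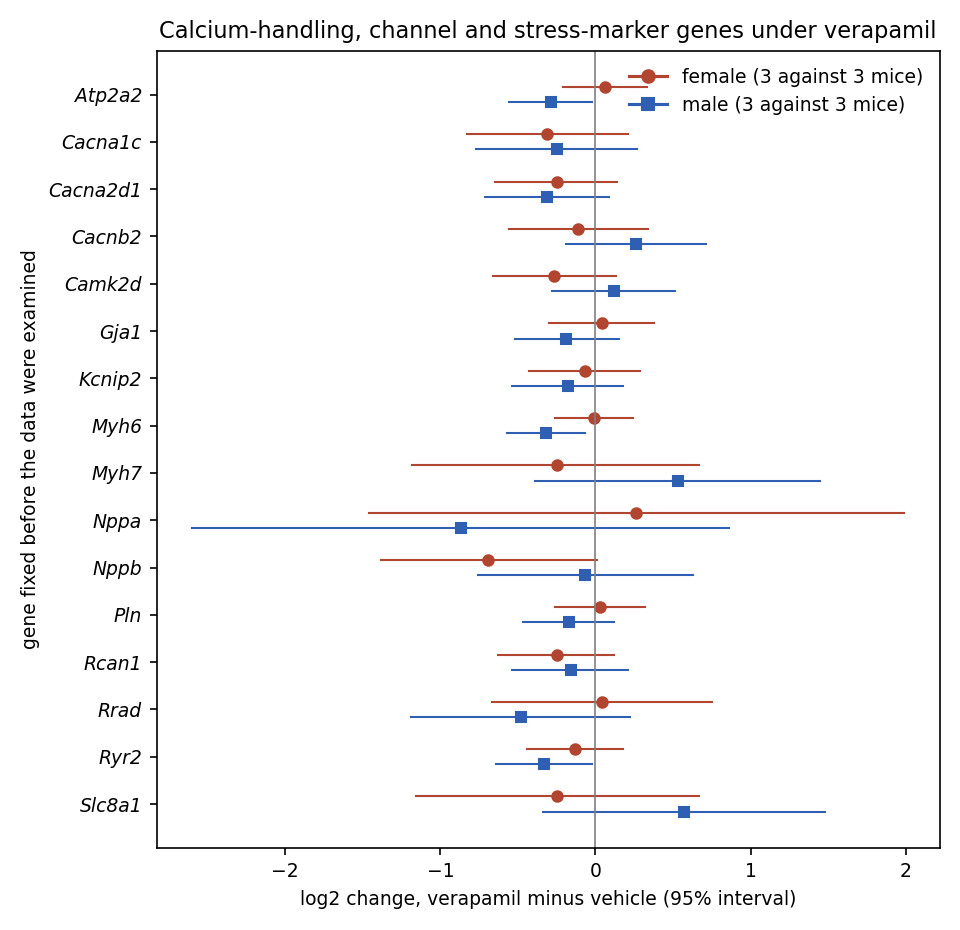
Each point is the verapamil minus vehicle difference of 1 gene fixed in advance, in log2 units, in females and in males, and the bars are 95% confidence intervals. Nppb is lowest among females (-0.69), and Ryr2, Atp2a2 and Myh6 lie at -0.33, -0.29 and -0.32 in males. The other probe set of Ryr2 had the opposite sign. In males 50 bright genes of no list had a median of -0.21, which was 0.02 after quantile normalization.

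The male comparison asked the same question in male mice. Genes of the contractile machinery fell together: 23 of 25 sarcomere and Z-disc genes were lower under verapamil, by a median of 0.27 log2 units, and the median was -0.04 after quantile normalization, which ended the call (camera, adjusted p = 6.92e-14; adjusted p = 0.144 with an estimated correlation). The sarcomere score was 0.08 in each vehicle male and between -0.14 and -0.08 in the verapamil males, so that 3 of 3 lay below every vehicle array. Tropomyosin, Tpm1, differed by -0.37 (SE 0.11), cardiac myosin-binding protein C, Mybpc3, by -0.34 (SE 0.10), the ventricular light chain Myl2 by -0.34 (SE 0.12) and Myh6, the main myosin of the adult mouse heart, by -0.32 (SE 0.12). Respiratory chain and ATP synthase genes fell by a median of 0.21, with 65 of 66 lower, and the median was -0.001 after quantile normalization (adjusted p = 7.3e-24; adjusted p = 0.437 with an estimated correlation). Ndufa13 of complex I, Cox6a2, the muscle form of a cytochrome oxidase subunit, and Uqcrb of complex III differed by -0.51 (SE 0.13), -0.38 (SE 0.14) and -0.33 (SE 0.12). In the respiratory score 2 of 3 verapamil arrays lay below every vehicle array.

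Other genes of energy supply were lower in males as well. In the glycolysis score 3 of 3 verapamil arrays lay below every vehicle array, and 2 in the tricarboxylic acid cycle and ribosomal scores. In the fatty acid score 1 lay below and 1 above every vehicle array. Genes of the tricarboxylic acid cycle fell by a median of 0.16, with 11 of 13 lower (adjusted p = 9.91e-04; adjusted p = 0.437 with an estimated correlation). They included citrate synthase, Cs, at -0.25 (SE 0.12). Glucose uptake and glycolysis genes fell by 0.13, with 16 of 21 lower (adjusted p = 0.00289; adjusted p = 0.437 with an estimated correlation). They included phosphofructokinase, Pfkm, at -0.28 (SE 0.11). Fatty acid uptake and oxidation genes fell by 0.17, with 21 of 29 lower (adjusted p = 0.00359; adjusted p = 0.498 with an estimated correlation). They included Hadhb at -0.28 (SE 0.12), Acadvl at -0.30 (SE 0.14) and the fatty acid carrier Fabp3 at -0.25 (SE 0.13). Ribosomal protein genes fell by a median of 0.12, with 29 of 37 lower, and turned to 0.04 after quantile normalization (adjusted p = 0.0017; adjusted p = 0.695 with an estimated correlation). They included Rps14 at -0.25 (SE 0.13). Quantile normalization ended the calls of the cycle, glycolysis and fatty acid lists (medians -0.02, 0.00 and -0.04), the cycle call ended without male vehicle 2 (-0.11), glycolysis without male verapamil 2 (-0.12), fatty acid genes without male vehicle 1, male vehicle 2 or male verapamil 3 (-0.09, -0.14 and -0.01) and ribosomal genes without male vehicle 1, male verapamil 2 or male verapamil 3 (-0.07, -0.09 and -0.06). The cycle median was -0.10 without male verapamil 3, and without male verapamil 1 the glycolysis and ribosomal medians were -0.22 and -0.195. Of 14 alternatives in males 12 kept the cycle call, 11 the glycolysis call, 7 the ribosomal call and 6 the fatty acid call. The last 2 also ended with the actin ratio as a covariate (-0.05 and -0.09). The estimated correlation, which ended every call, was not among the 14. Of these 14, the settings without the 3 arrays of highest actin ratio or of highest atrial markers leave out male vehicle 1 alone among the males, and repeat its medians. With no filter the glycolysis and fatty acid calls ended as well (-0.13 and -0.17).

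Markers of several cell types of the heart other than cardiomyocytes rose in males, with overlap of the arrays. Of the 3 verapamil arrays, 1 lay above every vehicle array in the macrophage score and 2 in the fibroblast score. In the endothelial score 2 lay above and 1 below every vehicle array, and in the mesothelial score 2 lay below. Macrophage markers rose by a median of 0.31, with 11 of 12 higher (adjusted p = 0.00108; adjusted p = 0.437 with an estimated correlation). Examples were the scavenger receptor Cd163 at 0.69 (SE 0.30) and Lyz2 at 0.36 (SE 0.17). Fibroblast markers rose by 0.30, with 10 of 11 higher (adjusted p = 0.0017; adjusted p = 0.437 with an estimated correlation). Examples were Tcf21 at 0.44 (SE 0.19) and Mfap5 at 0.63 (SE 0.30). Endothelial markers rose by 0.16, with 10 of 14 higher (adjusted p = 0.046; adjusted p = 0.557 with an estimated correlation). Examples were the receptor Tek at 0.40 (SE 0.18) and Pecam1 at 0.56 (SE 0.25). Mesothelial markers fell by a median of 0.31, with 8 of 8 lower (adjusted p = 0.0017; adjusted p = 0.437 with an estimated correlation), and Upk3b went from 11.94 ± 0.52 to 11.10 ± 0.91 (-0.85, SE 0.39). The endothelial, fibroblast and mesothelial calls ended without male vehicle 1 (0.12, 0.15 and -0.24), which had the highest actin ratio, the endothelial and macrophage calls without male vehicle 2 (0.09 and 0.15), the endothelial, fibroblast and macrophage calls without male verapamil 2 (0.10, 0.165 and 0.17) and the endothelial call without male verapamil 3 (0.06). Without male vehicle 3 the endothelial and macrophage medians were 0.27 and 0.50, and without male verapamil 1 the fibroblast and mesothelial medians were 0.51 and -0.52. The endothelial, fibroblast and mesothelial calls also ended with the actin ratio as a covariate (0.14, 0.15 and -0.20). The endothelial call ended further after quantile normalization (0.14), with no intensity trend (0.16) and with the mean of all probe sets of a gene (0.16). Of the 14 alternatives 4 kept the endothelial call, 9 the fibroblast, 10 the mesothelial and 12 the macrophage call, where 2 of the 14 repeat the omission of male vehicle 1.

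In the limma test 0 of 22518 probe sets had an adjusted p under 0.05 in males, and 612 (2.72%) had an unadjusted p under 0.05, 305 higher and 307 lower. The smallest p belonged to Vangl2, a planar cell polarity protein, at 4.89 ± 0.39 in vehicle and 7.06 ± 0.13 in verapamil males (2.17, SE 0.34, adjusted p = 0.49, higher in 3 of 3 arrays). Its value in vehicle males lay under 6.51, the level of the filter on dim probe sets. The same vehicle males enter the interaction and the comparison of the vehicle sexes. Next among the higher genes came the adhesion molecule Ceacam1 (1.09, SE 0.27), Prps2 of nucleotide synthesis (1.58, SE 0.39), the 14-3-3 protein Ywhaq (0.64, SE 0.16) and Trim34a (2.38, SE 0.63). Lower were AY036118 (-0.94, SE 0.22), Gpd1, glycerol-3-phosphate dehydrogenase, in 1 of its 3 probe sets (-1.56, SE 0.38; 0.26 and 0.10 in the others), Trim12c (-3.29, SE 0.82), the antiproliferative gene Btg2 (-0.81, SE 0.22) and Ndufa13. Of the genes fixed in advance, Ryr2 was at 13.95 ± 0.16 and 13.62 ± 0.06 (-0.33, SE 0.15) and Atp2a2 at 15.17 ± 0.07 and 14.88 ± 0.16 (-0.29, SE 0.13). Cacna1c differed by -0.25 (SE 0.24), Cacna2d1 by -0.31 (SE 0.18), Cacnb2 by 0.26 (SE 0.21), Rrad, which inhibits the L-type channel, by -0.48 (SE 0.33) and Slc8a1 by 0.57 (SE 0.42). Pln, Camk2d, Rcan1, Kcnip2 and Gja1 differed by -0.17, 0.12, -0.16, -0.18 and -0.19, Nppb by -0.07 (SE 0.32), Nppa by -0.87 (SE 0.80) and Myh7 by 0.53 (SE 0.43). All of these had an adjusted p of 1 except Vangl2. The other tested probe sets of Ryr2, Slc8a1, Kcnip2, Rcan1 and Camk2d all had the opposite sign. For comparison, 50 bright genes of no list (at least 14.25 log2 units) had a median male change of -0.21, and of 0.02 after quantile normalization.

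The averaged comparison asked what verapamil changed on average over the sexes, with each sex set against its own vehicle mice. Macrophage markers rose by a median of 0.28, with 11 of 12 higher (camera, adjusted p = 1.88e-06; adjusted p = 0.34 with an estimated correlation), with Fcgr1 at 0.42 (SE 0.20), Lyz2 at 0.39 (SE 0.12) and Adgre1 at 0.38 (SE 0.15). Fibroblast markers rose by 0.22, with 10 of 11 higher (adjusted p = 2.08e-04; adjusted p = 0.34 with an estimated correlation), and Tcf21, at 0.41 (SE 0.14), was higher without overlap in both sexes. The NRF2 and xenobiotic genes rose by 0.12, with 13 of 15 higher (adjusted p = 0.00156; adjusted p = 0.33 with an estimated correlation), and Cyp2e1 at 1.48 (SE 0.36) and Abcb1b at 0.67 (SE 0.17) passed when adjusted over the list alone. The Abcb1b difference lay almost wholly in the females. Matrix genes rose by 0.15, with 26 of 33 higher (adjusted p = 0.00425; adjusted p = 0.722 with an estimated correlation). Examples were Timp1 at 0.56 (SE 0.20), periostin, Postn, at 0.52 (SE 0.28) and the proteoglycan Lum at 0.34 (SE 0.16). Mesothelial markers rose by 0.27, with 8 of 8 higher (adjusted p = 0.0212; adjusted p = 0.541 with an estimated correlation), as the mean of a higher value in females and a lower one in males. The fibroblast median was 0.08, 0.12, 0.35 and 0.14 without female verapamil 2, male vehicle 1, male vehicle 3 or male verapamil 2, with the call kept, and the NRF2 median 0.19 without female verapamil 3. The matrix call ended without any 1 of female vehicle 1, female verapamil 1, female verapamil 2, male vehicle 1, male vehicle 2, male verapamil 2 or male verapamil 3 (0.06 to 0.10), and was 0.29, 0.24 and 0.245 without female verapamil 3, male vehicle 3 or male verapamil 1. The mesothelial call ended without any 1 of female vehicle 1, female vehicle 3, female verapamil 1, male vehicle 2, male vehicle 3 or male verapamil 1 (0.15 to 0.25), and its median was 0.48 without female vehicle 2. Without the 3 arrays of highest actin ratio the NRF2, matrix and mesothelial calls ended (0.085, -0.004 and 0.25). Of 20 alternatives, with the estimated correlation set aside, all 20 kept the macrophage and fibroblast calls, 19 the NRF2 call, 11 the mesothelial call and 10 the matrix call. The matrix call also ended with the actin ratio as a covariate (0.05), and the mesothelial call without the 3 arrays of highest atrial markers (0.23).

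Sarcomere genes fell by a median of 0.13 on average over the sexes, with 22 of 25 lower (camera, adjusted p = 8.97e-08). With an estimated correlation the adjusted p was 0.33, and after quantile normalization the median was -0.04. Before quantile normalization the fall lay in the males: the median was -0.01 in females (adjusted p = 0.549) and -0.27 in males. The difference between the sexes was called, but its adjusted p was 0.417 with an estimated correlation. After quantile normalization the male median was -0.04, with the call ended, and the female minus male median was -0.03. Quantile normalization makes the bright values of all arrays alike, so whether the fall was particular to males cannot be told. Examples of the averaged fall were Myom2 of the M-band at -0.32 (SE 0.10) and Mybpc3 at -0.20 (SE 0.07). Respiratory chain genes fell by 0.07, with 61 of 66 lower (adjusted p = 2.44e-06; adjusted p = 0.722 with an estimated correlation), as the mean of a higher value in females (0.06) and a lower one in males (-0.21). They included Ndufv1 of complex I at -0.23 (SE 0.08). Tricarboxylic acid cycle genes fell by 0.11, with 12 of 13 lower (adjusted p = 0.00154; adjusted p = 0.34 with an estimated correlation). They included Ogdh at -0.23 (SE 0.09). Fatty acid genes fell by 0.11, with 23 of 29 lower (adjusted p = 0.00203; adjusted p = 0.521 with an estimated correlation). They included Ppargc1a, a regulator of mitochondrial genes, at -0.25 (SE 0.11). Glycolysis genes fell by 0.10, with 14 of 21 lower (adjusted p = 0.0242; adjusted p = 0.34 with an estimated correlation). They included Pfkm at -0.19 (SE 0.08) and hexokinase 2, Hk2, at -0.21 (SE 0.11). Quantile normalization ended the respiratory and glycolysis calls (-0.01 and -0.03), and the respiratory call also ended without female verapamil 2 (-0.03), the cycle call without female verapamil 1 (-0.07), the fatty acid call without female verapamil 2 or male verapamil 3 (-0.09 and -0.08) and the glycolysis call without any 1 of female vehicle 1, female vehicle 2, female verapamil 1, female verapamil 2, male vehicle 1, male vehicle 3, male verapamil 2 or male verapamil 3 (-0.09 to -0.06). The respiratory median was -0.05, -0.16 and -0.13 without female verapamil 1, female verapamil 3 or male verapamil 1, where the fatty acid median was -0.17. Without the 3 arrays of highest actin ratio the respiratory, cycle, fatty acid and glycolysis calls ended (-0.008, -0.09, -0.11 and -0.08), and the glycolysis call also ended with no filter (-0.10), no intensity trend (-0.10) and the actin ratio as a covariate (-0.05). Of the 20 alternatives all 20 kept the sarcomere call, 17 the cycle call, 17 the fatty acid call, 16 the respiratory call and 6 the glycolysis call.

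Calcineurin, NFAT and MEF2 genes fell by a median of 0.09 on average over the sexes, with 17 of 22 lower (adjusted p = 0.0242; adjusted p = 0.541 with an estimated correlation). They included Rcan1 at -0.21 (SE 0.12) and the calcineurin subunit Ppp3cb at -0.16 (SE 0.09); the other tested probe sets of both genes had the opposite sign. The list median was -0.13 in females and 0.008 in males. Potassium and pacemaker channel genes fell by 0.09, with 13 of 20 lower (adjusted p = 0.0426; adjusted p = 0.33 with an estimated correlation). They included Abcc8, a subunit of the ATP-sensitive potassium channel, at -0.31 (SE 0.12) and Kcnj3 at -0.59 (SE 0.29). The calcineurin call ended without any 1 of female vehicle 1, female verapamil 2, female verapamil 3, male vehicle 1, male vehicle 2, male verapamil 1 or male verapamil 3 (-0.12 to -0.004) and was -0.155 without female verapamil 1. The potassium channel call ended without any 1 of female vehicle 2, female vehicle 3, female verapamil 1, female verapamil 3, male vehicle 1, male vehicle 2, male verapamil 1, male verapamil 2 or male verapamil 3 (-0.11 to -0.04) and was -0.15 and -0.06 without female vehicle 1 or male vehicle 3. Both calls also ended with the mean of all probe sets of a gene (-0.04 and -0.05) and without the 3 arrays of highest atrial markers (-0.05 and -0.08), and the calcineurin call with the actin ratio as a covariate (-0.07). The potassium channel call ended further after quantile normalization (-0.10), with no filter (-0.075), with no intensity trend (-0.09) and without the 3 arrays of highest actin ratio (-0.15). Of the 20 alternatives 10 kept the calcineurin call and 4 the potassium channel call.

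For the averaged change 0 of 22518 probe sets passed the limma test, and 716 (3.18%) had an unadjusted p under 0.05, 410 higher and 306 lower. Ywhaq had the smallest p, at 0.58 (SE 0.11), and went from 11.56 ± 0.17 to 12.08 ± 0.05 in females and from 11.47 ± 0.23 to 12.10 ± 0.19 in males. Pla2g4a, the cytosolic phospholipase A2, at 0.62 (SE 0.14), the small GTPase Rab32 at 1.00 (SE 0.24) and Iah1 at 0.88 (SE 0.20) were also higher without overlap in both sexes. Glycogen phosphorylase B, Pygb, was lower without overlap in both sexes, from 13.63 ± 0.13 to 13.31 ± 0.08 in females and from 13.76 ± 0.10 to 13.36 ± 0.02 in males (-0.36, SE 0.08). Ubox5 (-1.26, SE 0.30), C330022C24Rik (-1.11, SE 0.27), Rpl41 (-0.40, SE 0.10) and Slc1a1 (-1.02, SE 0.27) followed. Cacna1c and Cacna2d1 had averaged differences of -0.28 (SE 0.17) and -0.28 (SE 0.13), Ryr2 of -0.23 (SE 0.10) and Nppb of -0.38 (SE 0.23), and each of these genes had an adjusted p of 1. The other probe set of Ryr2 had the opposite sign.

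The interaction asked where the verapamil effect differed between females and males, as the female effect minus the male effect. Of the lists called, mesothelial markers differed most: all 8 were more positive in females, by a median of 1.31 log2 units (camera, adjusted p = 6.14e-14; adjusted p = 0.128 with an estimated correlation), and 5 of the 8 passed when adjusted over the list alone. The difference was 2.40 (SE 0.55) for Upk3b, 2.05 (SE 0.60) for Lrrn4, 1.68 (SE 0.51) for Krt18 and 1.27 (SE 0.43) for Krt19. Sarcomere genes differed by a median of 0.22, with 20 of 25 positive, and by -0.03 after quantile normalization (adjusted p = 3.32e-07; adjusted p = 0.417 with an estimated correlation). Examples were Tpm1 at 0.42 (SE 0.15) and Myl2 at 0.39 (SE 0.17). Respiratory chain genes differed by 0.28, with 64 of 66 positive (adjusted p = 5.04e-23; adjusted p = 0.611 with an estimated correlation). An example was Ndufa13 at 0.62 (SE 0.19). Ribosomal protein genes differed by 0.23, with 31 of 37 positive (adjusted p = 1.49e-07; adjusted p = 0.686 with an estimated correlation). An example was Rps14 at 0.35 (SE 0.18). Quantile normalization ended the respiratory and ribosomal calls (0.01 and 0.007), which also ended without the 3 arrays of highest atrial markers (0.045 and -0.06). Without female verapamil 3 the ribosomal call ended (0.06) and the respiratory median was 0.15, and without female verapamil 2 the ribosomal median was 0.37. Of 20 alternatives all 20 kept the mesothelial call, 19 the sarcomere call, 18 the respiratory call and 17 the ribosomal call. The estimated correlation, which ended every call, was not among these 20.

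Interferon response genes differed by a median of 0.28 between the sexes, with 19 of 22 more positive in females (adjusted p = 0.0101; adjusted p = 0.686 with an estimated correlation). An example was Oasl2 at 0.63 (SE 0.36). Immediate early genes differed by 0.14, with 14 of 22 positive (adjusted p = 0.0462; adjusted p = 0.686 with an estimated correlation). Among these Btg2 passed when adjusted over the list alone: it was at 9.36 ± 0.27 and 10.06 ± 0.08 in vehicle and verapamil females and at 10.40 ± 0.41 and 9.59 ± 0.16 in males (1.51, SE 0.30). Heat shock genes differed by -0.17, with 13 of 16 more positive in males (adjusted p = 0.0116; adjusted p = 0.611 with an estimated correlation), and the inducible chaperone genes Hspa1a and Hspa1b differed by -2.03 (SE 0.96) and -2.12 (SE 1.05), with 10.56 and 12.72 log2 units in male verapamil 2 against 6.65 and 8.23 in male verapamil 1. The interferon call ended without female vehicle 3, female verapamil 2, female verapamil 3 or male verapamil 1 (0.15 to 0.22), its median turned to -0.13 without male vehicle 3 and was 0.46 without male vehicle 2, and the heat shock call ended without female vehicle 1, female verapamil 2, male vehicle 2, male vehicle 3 or male verapamil 2 (-0.17 to -0.11) and was -0.27, -0.10, -0.26 and -0.27 without female vehicle 2, female vehicle 3, female verapamil 3 or male vehicle 1. The immediate early call ended without female vehicle 1, female vehicle 2, female verapamil 2, male vehicle 2, male vehicle 3 or male verapamil 1 (0.03 to 0.23) and female verapamil 1 (-0.04), and was 0.29, 0.28 and 0.28 without female verapamil 3, male vehicle 1 or male verapamil 3 and 0.41 without the 3 arrays of highest atrial markers. It also ended with no filter (0.21), no intensity trend (0.14), the mean of all probe sets of a gene (0.13) and without the 3 arrays of highest actin ratio (0.115), and the interferon call with no filter (0.285) and without the 3 arrays of highest atrial markers (0.30). Of the 20 alternatives 14 kept the heat shock call, 13 the interferon call and 8 the immediate early call.

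No difference between the sexes was called for the macrophage (adjusted p = 0.768), fibroblast (0.718), endothelial (0.173), matrix (0.851), NRF2 (0.216), calcineurin (0.503), fatty acid (0.503), glycolysis (0.122) or tricarboxylic acid cycle (0.216) genes. For single genes the limma test called 0 of 22518 probe sets, and 443 (1.97%) had an unadjusted p under 0.05. The smallest p belonged to Btg2 (1.51), followed in the same direction by Upk3b, Pmf1 (2.16, SE 0.50), Fbxo36 (1.67, SE 0.40) and Tmem119 (1.06, SE 0.26), and in the other by Vangl2 (-2.03, SE 0.48), Mzt1 (-1.01, SE 0.25), Klhdc4 (-1.30, SE 0.35), Cux1 (-1.21, SE 0.35) and Ceacam1 (-1.31, SE 0.38). Among the genes fixed in advance the differences were 0.36 (SE 0.18) for Atp2a2, 0.31 (SE 0.16) for Myh6, 0.20 (SE 0.21) for Ryr2, -0.62 (SE 0.46) for Nppb and -0.06 (SE 0.34) for Cacna1c. The other probe sets of Fbxo36 and Cacna1c had the opposite sign. Over 11502 genes the female and male changes had a Pearson correlation of 0.111 and a Spearman correlation of 0.13, and 54.9% of genes had the same sign in both sexes.

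**Figure D3:**
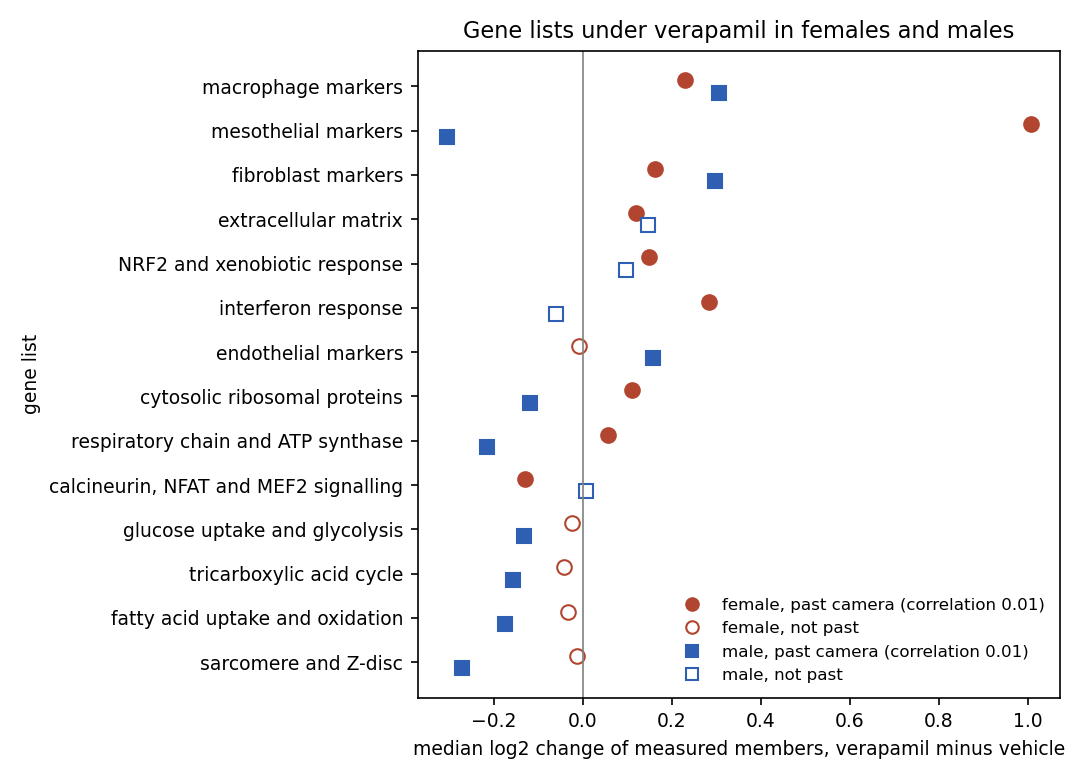
Each point is the median log2 change under verapamil of the measured genes of a list, in females and in males, with filled points for lists past camera. Mesothelial markers lie at 1.01 in females and -0.31 in males, and respiratory chain genes at 0.06 and -0.21, which were -0.003 and -0.001 after quantile normalization.

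The comparison of vehicle-treated males and females checked the sex of the mice and asked which genes differ by sex in the ventricle without verapamil. Xist, the RNA that silences 1 X chromosome in females, was at 11.18 ± 0.07 in females and 6.50 ± 0.69 in males (-4.68, SE 0.39, adjusted p = 7.4e-05). The Y-linked genes Eif2s3y (3.30 ± 0.31 and 10.29 ± 0.59; 6.99, SE 0.36, adjusted p = 7.9e-07) and Uty (4.91 ± 0.43 and 8.89 ± 0.20; 3.97, SE 0.30, adjusted p = 3.8e-05) were higher in males, and in all 3 genes the arrays of the sexes did not overlap. In the limma test 7 probe sets passed, 6 higher and 1 lower in males, for these 3 genes and 3 probe sets without a gene name (at 8.14, 5.69 and 6.70), and 558 (2.48%) had an unadjusted p under 0.05. Kdm5d, left out by the filter on dim probe sets, lay between 8.50 and 9.16 in males and between 2.99 and 5.43 in females, so that all 12 arrays had the sex of their label. Genes that escape X inactivation had lower values in males without a call, at -0.71 (SE 0.29) for Kdm6a, -0.61 (SE 0.23) for Kdm5c, -0.71 (SE 0.15) for Eif2s3x and -0.37 (SE 0.17) for Ddx3x.

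Other genes did not pass between the sexes. Vangl2 (-2.15, SE 0.34, adjusted p = 0.069), Igfbp3, which binds insulin-like growth factors (-1.25, SE 0.24, adjusted p = 0.29), and Abca4 (-2.47, SE 0.51) were lower in 3 of 3 males than in every female. The Vangl2 difference rests on the same dim vehicle males as its male and interaction differences. Hsd11b1, which regenerates active glucocorticoid (1.20, SE 0.22, adjusted p = 0.21), Aldh1a1 of retinoic acid synthesis (1.15, SE 0.22, adjusted p = 0.30), Pmf1 (1.77, SE 0.35), Btg2 (1.04, SE 0.22) and Hfe, a regulator of iron uptake (0.89, SE 0.18), had higher values in males.

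As groups, mesothelial markers were higher in vehicle males by a median of 0.55, with 8 of 8 higher (camera, adjusted p = 1.66e-06; adjusted p = 0.388 with an estimated correlation). An example was Upk3b at 1.02 (SE 0.39). The mesothelial scores of female vehicle 1, 2 and 3 were -0.55, 0.17 and -0.88. The same vehicle arrays enter the mesothelial changes under verapamil and the interaction, so that these results are not separate from each other. Macrophage markers were higher by 0.22, with 12 of 12 higher (adjusted p = 8.29e-04; adjusted p = 0.609 with an estimated correlation). An example was Csf1r at 0.30 (SE 0.21). Inflammation genes were higher by 0.25, with 11 of 17 higher (adjusted p = 0.00661; adjusted p = 0.388 with an estimated correlation). Examples were the eosinophil attractant Ccl11 at 0.84 (SE 0.23) and Serpina3n at 1.03 (SE 0.40). Interferon genes were higher by 0.21, with 17 of 22 higher (adjusted p = 0.0166; adjusted p = 0.837 with an estimated correlation). Without male vehicle 3 the macrophage, inflammation and interferon calls ended, at 0.03, 0.05 and a reversed -0.21, the inflammation call also ended without female vehicle 1 (0.195) and was 0.14 without female vehicle 3, and the interferon call ended without female vehicle 3 (0.10). Without male vehicle 2 the macrophage and interferon medians were 0.33 and 0.37, and the mesothelial median was 0.93 and 0.28 without female vehicle 2 or female vehicle 3 and 0.22, with the call ended, without the 3 arrays of highest atrial markers. With no filter the inflammation and interferon calls ended (0.19 and 0.21). The interferon call also ended with the mean of all probe sets of a gene (0.18) and without the 3 arrays of highest atrial markers (0.205). Of 13 alternatives 12 kept the mesothelial call, 12 the macrophage call, 10 the inflammation call and 8 the interferon call. The estimated correlation, which ended every call, was not among these 13.

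Immediate early genes were higher in vehicle males by 0.13, with 15 of 22 higher (adjusted p = 8.29e-04; adjusted p = 0.656 with an estimated correlation). Of these Nr4a1 was at 0.98 (SE 0.39), and Btg2 passed when adjusted over the list alone. The Btg2 difference rests on the same vehicle mice as its interaction difference. Glucocorticoid-responsive genes were higher by 0.15, with 16 of 20 higher (adjusted p = 8.29e-04; adjusted p = 0.388 with an estimated correlation). Examples were Fkbp5 at 0.71 (SE 0.32) and Tat at 0.95 (SE 0.43). Genes of the endoplasmic reticulum stress response were lower by 0.14 in males (median -0.14), with 16 of 20 lower (adjusted p = 0.0353; adjusted p = 0.388 with an estimated correlation). Examples were Manf at -0.70 (SE 0.30) and the chaperone Hspa5 at -0.35 (SE 0.22). Respiratory chain genes were higher by 0.06, with 61 of 66 higher (adjusted p = 6.72e-04; adjusted p = 0.887 with an estimated correlation), and sarcomere genes by 0.06, with 22 of 25 higher (adjusted p = 0.0144; adjusted p = 0.656 with an estimated correlation). The immediate early and glucocorticoid calls ended without male vehicle 3 (0.03 and 0.04), the stress call without any 1 of female vehicle 1, female vehicle 3, male vehicle 1, male vehicle 2 or male vehicle 3 (-0.185 to -0.05), and the respiratory and sarcomere calls after quantile normalization (0.02 and 0.003) and without female vehicle 3 (0.00 and 0.004) or male vehicle 1 (0.04 and 0.05). The immediate early median was 0.23 and 0.21 without female vehicle 2 or male vehicle 1, the respiratory median 0.10 and 0.11 without female vehicle 1 or female vehicle 2, and the sarcomere median 0.095 without female vehicle 2. The stress call also ended after quantile normalization (-0.14), with no intensity trend (-0.14), with the mean of all probe sets of a gene (-0.12) and without the 3 arrays of highest actin ratio (-0.15) or of highest atrial markers (-0.12). The sarcomere call ended with no filter and no intensity trend (0.06 in both) and without the 3 arrays of highest actin ratio (0.05) or of highest atrial markers (0.02). Without the latter arrays the respiratory median turned to -0.03. Of the 13 alternatives 12 kept the immediate early call, 12 the glucocorticoid call, 9 the respiratory call, 6 the sarcomere call and 3 the stress call.

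Of the 39 lists, 34 had enough measured genes for camera, and 14 passed in no comparison. These 14 held the L-type and T-type channel genes with their RGK regulators (median -0.11 in females and -0.045 in males over 11 genes), the genes of sarcoplasmic reticulum and calcium handling (-0.07 and -0.003 over 25 genes, smallest adjusted p = 0.0995, in males), sodium channels, fetal and hypertrophy markers, the circadian clock, hypoxia, cell cycle, protein turnover and adrenergic signalling, and the markers of atrial muscle, smooth muscle, skeletal muscle, neutrophils and nerve. Their medians lay between -0.16 and 0.54 in females, -0.78 and 0.17 in males and -0.21 and 0.48 between the sexes. Of the 123 list tests that did not pass, 22 had a median or mean against the direction of the test, and of the 47 that passed 0 had. Red blood cell, adipocyte, lymphocyte, Y-linked and X-escape lists had too few measured genes for the test.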

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

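The tests of mesothelial surface tissue, of the share of cardiomyocytes and of 50 bright genes of no list, and the alternatives without the arrays of highest actin ratio or atrial markers, were chosen only after the results were seen. In 7 gene lists the verapamil effect differed between females and males by camera, with an adjusted p under 0.05 at the preset correlation and above it in each list with an estimated correlation. The median differences, female minus male, were 1.31 for mesothelial markers, 0.28 for the respiratory chain and ATP synthase, 0.23 for ribosomal proteins, 0.22 for sarcomere and Z-disc genes, 0.28 for the interferon response, 0.14 for immediate early genes and -0.17 for the heat shock response. After quantile normalization the respiratory, ribosomal and sarcomere medians were 0.01, 0.007 and -0.03, with all 3 calls ended, and the interferon median turned to -0.13 without male vehicle 3. The number of 7 lists was reached or passed in 49 of 100 splits of the arrays, with 15 lists in the highest other split, so that chance was not excluded for the number of lists.

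Mesothelial markers were higher under verapamil in females and lower in males, by a median difference of 1.31 over 8 of 8 genes. Arrays with a high actin 3' to 5' ratio as the whole cause are argued against by the median of 0.89, with 7 of 8 genes positive, without the 3 arrays of highest ratio. A candidate explanation that stays open is a different amount of mesothelial surface tissue in the samples. Between mice of the same group the 8 genes varied together, with a median pairwise correlation of 0.48. This lay above 0.27, the 95th percentile of 10000 random lists of equal size and brightness (median 0.02). Joint regulation would also make the genes vary together, so this test cannot tell the 2 apart. The correlation estimated for camera was 0.44 for this list and lower for most others. It was higher for respiratory chain (0.74), ribosomal (0.67), interferon (0.51), matrix (0.49) and neutrophil (0.46) genes. The list consists of markers of this cell layer alone, its brightest gene Upk3b had 10.93 to 12.48 log2 units in the group means, and a dissection of the free wall includes the surface. A sex-dependent response to verapamil also stays open and was not tested apart from the amount of tissue.

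Sarcomere and respiratory chain genes were lower under verapamil in males, by medians of -0.27 and -0.21, which were -0.04 with 17 of 25 genes negative and 0 with 33 of 66 negative after quantile normalization. An intensity-dependent scale difference between arrays cannot be told apart from a change of these bright genes: 50 bright genes of no list had a median of -0.21 before and 0.02 after it, while ribosomal protein genes, which were predicted to fall by at least as much, fell by only 0.12 but are dimmer (13.36 log2 units in vehicle males against 14.20 and 14.52). A smaller share of cardiomyocytes would raise the markers of every other cell type alike, and in males the mean of the fibroblast, endothelial, smooth muscle and macrophage scores minus the mesothelial score differed by 0.60 (SE 0.34). The lowest verapamil array was at -0.19 and the highest vehicle array at 0.10, and this overlap of the 6 arrays keeps a smaller share open: it cannot be told apart from a change within the cells. A response of male heart muscle to verapamil stays open as well and was not tested apart from these.

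Sln, the gene of sarcolipin, an inhibitor of the calcium pump in atrial muscle, was left out by the filter on dim probe sets and reached 12.78 log2 units in female verapamil 3, above the highest vehicle array (10.73, in female vehicle 3). These arrays also had the highest atrial scores, at 1.56 and 0.81. An effect of verapamil on Sln was not tested apart from the atrial markers.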

How the results depend on the processing

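The alternatives without the 3 arrays of highest actin 3' to 5' ratio, without the 3 of highest atrial markers and with the actin ratio as a covariate, and leaving out arrays for the correlation of the sexes, were chosen only after the results were seen. For probe sets past limma, the block by replicate number gave 1 in females, averaged and for the interaction (Iqcg) in place of 0, leaving out the high-actin arrays gave 1 in females (Iqcg), only the male arrays gave 2 in males (Cyfip2), single arrays left out gave 0 to 2 in males (Trim12c and Trim68 without male verapamil 2), and the filter at the 75th percentile gave 0 in place of 7 between vehicle males and females. No list passed with an estimated correlation, 0 in all 5 comparisons. The number of lists was 4 to 12 in females, 6 to 16 in males, 7 to 13 averaged and 4 to 9 for the interaction over single arrays left out, 6 in males after quantile normalization and 7 averaged without the high-actin arrays. Female vehicle 1, without a number in its label, and female verapamil 1 each stood alone in a block by replicate number. The female effect under the block therefore rests on the female arrays numbered 2 and 3, as it does without the high-actin arrays. The block by replicate number gave 6 lists in females in place of 9, 13 in males in place of 10, 8 averaged in place of 12 and 6 for the interaction in place of 7. Under it the matrix, NRF2 and fibroblast calls ended in females, the potassium channel, glycolysis, respiratory, tricarboxylic acid cycle, matrix and mesothelial calls averaged, and the immediate early and heat shock calls for the interaction; none of the 10 male calls ended. Medians that reversed were, for respiratory chain genes, -0.003 in females after quantile normalization, -0.15 there without the atrial arrays, -0.079 to 0.151 there over single arrays left out and -0.026 in the sex comparison without the atrial arrays; for ribosomal genes 0.036 in males after quantile normalization, -0.125 in females and -0.064 for the interaction without the atrial arrays and -0.052 to 0.22 in females over single arrays; for sarcomere genes -0.032 for the interaction after quantile normalization; and for interferon genes -0.13 to 0.46 for the interaction and -0.21 to 0.37 in the sex comparison over single arrays. The causes were not tested, except that single arrays and subsets leave fewer samples. Under other settings than single arrays left out, list calls kept direction and side of the threshold 264 times, weakened 143 times and reversed 7 times, and over single arrays 286, 105 and 5 times. Named genes did so 3456 times, with 137 changes of sign without a call, 7 gained and 1 lost call, and over single arrays 2463, 37, 2 and 0 times. Nearly all named genes had no call to lose, as limma called none under verapamil, so these numbers say little about robustness. Genes removed by a filter were not counted, which includes calls lost with the filter at the 75th percentile. Residuals of arrays with the same number correlated at 0.15, 0.08 and 0.13 in males and 0.18 and 0.12 in females, and as 1 pair lay under 0.1 the numbers were not taken to pair arrays. Female vehicle 1, without a number in its label, was left out of this check, and its residuals correlated at 0.32 with female verapamil 1. Male vehicle 1 correlated with these 2 arrays at 0.42 and 0.37. Not every array correlated best with the array of its own number. In every group the array called 1 had the highest actin 3' to 5' ratio (2.08, 1.77, 2.24 and 1.63). Shared processing of arrays by number was therefore not excluded. The main fit holds no block, so any such difference stays in its spread and can hide changes. The correlation of female and male changes lay between 0.029 and 0.165. The number of arrays limits the precision.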

Other observations

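The comparison of the female to male correlation with other splits, and the genes named in the next paragraphs, were chosen only after the results were seen. Adiponectin, Adipoq, and carbonic anhydrase 3, Car3, both abundant in fat cells, had lower values in vehicle males than in vehicle females. Adipoq was at 8.27 ± 0.37 in females and 6.14 ± 0.97 in males (mean ± SD, log2 units, n = 3; -2.13, SE 0.46, limma, adjusted p = 0.547), and Car3 at 10.71 ± 0.29 and 8 ± 1.43 (-2.72, SE 0.59, adjusted p = 0.547), each lower in 3 of 3 males. Under verapamil Adipoq differed by 0.87 in females and 1.16 in males and Car3 by 0.90 and 1.39, with averaged differences of 1.02 (SE 0.33) and 1.14 (SE 0.41). Other genes of fat metabolism, Fabp4 and Lipe, differed between the vehicle sexes by -0.02 (SE 0.13) and 0.07 (SE 0.20).

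Genes of atrial muscle and of the heat shock response were high in single arrays. Myl4 was at 13.41 log2 units in female verapamil 3, 11.49 in female vehicle 3 and 11.39 in male vehicle 1, and between 7.35 and 9.47 in the other 9 arrays. Hspa1b was at 12.72 in male verapamil 2 and 10.67 in male verapamil 3, and at 9.29 or lower in the other 10 arrays, and Dnaja1 at 12.87 and 12.22 in these arrays. Nppa was at 10.48 in male verapamil 1 and at 13.76 and 14.50 in the other male verapamil arrays. Trim12c (5.47 ± 2.34) and Trim68 (5.58 ± 1.95) in verapamil males and Iqcg (5.08 ± 2.49) in vehicle females also varied between arrays of the same group.

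The arrays were split again within the groups compared. In females and in males 6 arrays give only 10 splits, which are too few for a share under 0.05: for lists the real split gave 9 in females, the highest other 9 (2 of 10 as large), and 10 in males against 16 (2 of 10). The other female split with 9 lists set female vehicle 1, female vehicle 3 and female verapamil 3 against the rest, with the atrial genes high in the last 2, and the male split with 16 lists set male vehicle 1, male vehicle 2 and male verapamil 1 against the rest. Between vehicle males and females, again with 10 splits, the real split gave 7 probe sets against 0 in the highest other (1 of 10) and 9 lists against 8 (1 of 10). Averaged over the sexes the real split gave 12 lists against 14 (8 of 100), and for the interaction 7 lists against 15 (49 of 100), so that chance was not excluded for these 2 numbers. For the probe sets changed by verapamil the real number was 0, which every split reaches (10 of 10 in females and in males, 100 of 100 averaged and for the interaction), so that the splits tested nothing there; the highest other split gave 0 in females, 1 in males, 5 averaged and 5 for the interaction. The correlation of 0.111 between female and male changes was matched or passed in size by 38 of 100 splits, the highest other at 0.295, so that chance was not excluded for it either.

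Female vehicle 1, female verapamil 1 and male vehicle 1 stood apart from the other 9 arrays, and their split took 24% of the variance, the most of all 220 splits of 3 arrays. RNA or labelling that favours the 3' end of transcripts is a candidate explanation: loadings of this first component on pairs of probe sets of the same gene correlated at 0.14, against 0.58 and 0.34 for the 2 next components (5199 genes). More blood in these samples cannot be told apart from it, since the split took 4.7% of the variance and ranked 220 of 220 after the red blood cell score was removed, and 3.3% and 220 of 220 after the actin ratio was removed. No biological explanation was tested, as the 3 arrays belong to 3 groups.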
